A study of Mus musculus with 24 samples.

How the data were processed

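RNA of whole adipose tissue from male C57BL/6J mice was measured in 24 libraries. Per the labels' protocols, RNA was extracted with a NucleoSpin RNA kit, and stranded total RNA libraries were sequenced from both ends. The values the authors deposited are raw read counts per Ensembl gene, without normalisation, in 1 table per library. Per the submitters' processing notes, cutadapt, STAR and HTSeq 0.6.1p1 were used with the genome builds GRCm38 and mm10, which are names of the same build. Versions of cutadapt and STAR, the counting mode, the strand setting and the annotation release are not given in the sources used here.

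Each table lists 49585 gene identifiers, of which 49326 are in the GENCODE M21 annotation of GRCm38, which supplied symbols, types and coordinates. The other 259 held 0.0103% of the counts and were tested without a symbol. Total counts per library ranged from 31.96 to 46.62 megareads. A gene with 0 counts in a library may be present at up to 3 counts (95% confidence), and this floor covers counting error only, since reads without molecular identifiers are not independent molecules.

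Libraries were grouped by diet, genotype and depot as the labels give them. The titles carry replicate numbers or animal marks, and the labels do not state beyond these that libraries come from separate animals. The comparisons were diet in SAT, genotype in SAT, genotype in GAT, GAT against SAT in wild-type, and the difference of the genotype effect between depots. The comparisons, tests, gene lists and most alternative settings were fixed before the data were examined. Tests of the lists on the difference between depots and the alternatives that leave out or adjust for libraries with transcripts of other tissues were chosen after seeing the data.

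Genes were tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr (minimum count 10, minimum total count 15), TMM normalisation, and the quasi-likelihood test with robust fitting. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison. Positive log2 fold changes mean higher on the high-fat diet, in Azin2-/-, or in GAT. Means and SD in normalised CPM use the TMM factors, and Azin2 and marker levels per library are CPM of the total count. Groups that do not overlap were counted over all tested genes, beside the share that chance gives. Library sizes were compared by two-sided exact permutation tests.

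Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and needed at least 5 members past the filter. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes, and fry tests whether the genes of a list move one way on balance. The lists covered polyamine metabolism, cell cycle arrest and secreted factors, histone acetylation, adipocyte function and metabolism, immune, stromal and vascular cells, stress responses, the circadian clock, and markers of tissues next to fat. The neutrophil and epididymis lists had too few members past the filter in every comparison and were not tested, and lymph node stroma was tested only in GAT and in the difference between depots. List scores per library are means of log2 CPM with 0.5 CPM added.

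The diet signature held up to 200 genes of smallest p per direction among those called in the diet comparison, and was tested with camera in the genotype comparisons. Called genes within 10 Mb of Azin2 were compared with all other tested genes by a two-sided Fisher exact test.

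Named genes followed a rule. Azin2 is given in each comparison. Up to 5 genes per direction have the largest log2 fold change among called genes with a mean log2 CPM of at least 1, no overlap between groups, and an informative symbol of a gene that is not a pseudogene. Up to 3 called members of smallest p were taken from each list that was called or held a called gene, at most 20 per comparison. Where this gave under 10 genes, the 10 tested genes of smallest p were added. Cdkn1a, Cdkn2a, Odc1, Sat1, Lep, Adipoq, Ccl2 and Adgre1 are given in the main comparisons whatever their p. Genes named for another reason are said to be named after their values were seen.

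Alternatives were the size factors of DESeq2 1.42.0 within the edgeR fit, the DESeq2 Wald test, limma-voom with sample quality weights, no low-count filter, all 24 libraries in 1 fit, the replicate number or animal mark as a block, other windows and signature sizes, and leaving out each replicate in turn. The tests were tried on simulated data made from the counts of each design with known changes added. There, 4.35% to 7.20% of edgeR's calls were false in diet, SAT and the difference between depots, 2.07% in GAT and 8.63% between depots, against 18.8% to 36.8% for DESeq2. A list with added changes was called in each comparison, and 0 of 30 lists without change were. Counts were drawn there independently for each gene around a mean common to the libraries of a group. This tests neither lists whose genes move together nor groups that hold a library far from the others. Other groupings of the real diet libraries called up to 21 lists.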

Results

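Whole white adipose tissue of male C57BL/6J mice was profiled by RNA sequencing in 24 libraries that form 6 groups. In the diet experiment, subcutaneous adipose tissue (SAT) came from mice kept for 20 weeks on a high-fat diet with 60% of energy from fat (n = 4) or on a low-fat diet with 10% (n = 4). In the genotype experiment, mice lacking Azin2 (Azin2-/-) and wild-type littermates ate the high-fat diet for 8 weeks, and SAT (3 Azin2-/-, 5 wild-type) and epigonadal adipose tissue (GAT, 4 of each genotype) were taken. Total counts per library ranged from 31.96 to 46.62 megareads. Mean library size differed by -2.89 megareads between high-fat and low-fat SAT (two-sided exact permutation test, p = 0.171), by -2.58 megareads between Azin2-/- and wild-type SAT (exact p = 0.518) and by -1.40 megareads in GAT (exact p = 0.543). Leaving out each library in turn gave -3.98 to -1.95 megareads for diet (exact p of 0.0857 or more), -4.41 (without Azin2-/- replicate 1) to -0.364 (without Azin2-/- replicate 2) in SAT, and -3.44 (without Azin2-/- replicate 4) to 0.717 (without wild-type replicate 1) in GAT.

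Azin2 (ENSMUSG00000028789, a protein-coding gene on chromosome 4 from 128930233 to 128962442, minus strand, GRCm38) encodes an antizyme inhibitor that protects ornithine decarboxylase from antizyme and so favours polyamine synthesis. It was read at 11.5, 6.73 and 10.7 CPM (counts scaled to the library total) in Azin2-/- SAT replicates 1, 2 and 3. Wild-type SAT replicates 1 to 5 held 16.8, 25.9, 14.6, 25.8 and 18.0 CPM. In GAT, the library labelled Azin2-/- replicate 1 held 19.8 CPM and Azin2-/- replicates 2, 3 and 4 held 12.7, 14.8 and 12.9 CPM. Wild-type GAT replicates 1 to 4 held 26.1, 22.9, 26.6 and 24.6 CPM. Every library labelled Azin2-/- thus lay below every wild-type library of its depot, while reads over the whole gene persisted in each of them. Which part of the gene is deleted is not given in the sources used here, so reads from exons outside the deletion can remain. On the high-fat diet, SAT replicates 3 to 6 held 12.8, 12.8, 14.4 and 14.4 CPM, and on the low-fat diet replicates 1, 3, 5 and 6 held 18.0, 17.0, 19.5 and 22.5 CPM.

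**Figure D1:**
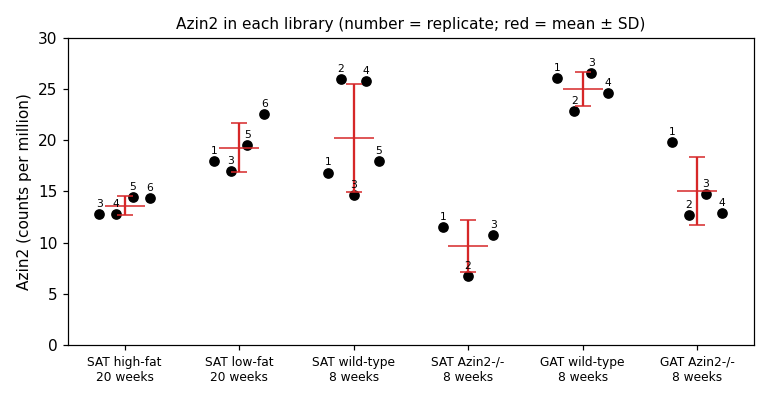
Azin2 in CPM (vertical axis) in each of the 24 libraries by group, with replicate numbers beside the points and the group mean ± SD in red. GAT libraries labelled Azin2-/- span 12.7 to 19.8 CPM, below the lowest wild-type GAT library at 22.9 CPM.

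Markers of neighbouring tissues were unevenly spread over the libraries. The summed level of 16 skeletal muscle genes was 79610 CPM in SAT Azin2-/- replicate 2, 71020 CPM in SAT wild-type replicate 3, 26070 CPM in low-fat replicate 5, 7397 CPM in high-fat replicate 6 and 1371 CPM in low-fat replicate 6. Epididymis genes summed to 50820 CPM in the library labelled SAT low-fat replicate 1 and to 5745 CPM in GAT wild-type replicate 3, against at most 1.10 CPM in the other libraries. In the library labelled SAT low-fat replicate 1, the epididymal lipocalin Lcn8 reached 5250 CPM. Its Hoxc10 and Tbx15, developmental transcription factors of subcutaneous fat, were at 0.047 and 0.117 CPM, against 25.5 to 31.5 CPM and 18.1 to 40.1 CPM in the other low-fat libraries.

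**Figure D2:**
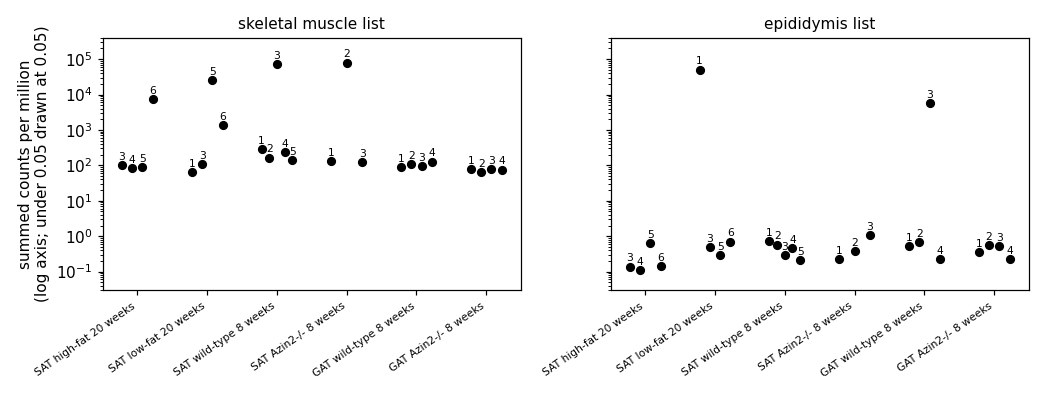
Summed CPM (log axis) of the skeletal muscle list (left) and the epididymis list (right) in each library by group, with replicate numbers beside the points. SAT Azin2-/- replicate 2 (79610) and SAT wild-type replicate 3 (71020) carry the most muscle transcripts, and the library labelled SAT low-fat replicate 1 (50820) the most epididymis transcripts.

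The first comparison asked what a long high-fat diet changes in SAT. Lists of macrophage, lipid-associated macrophage and proliferation genes were called higher in high-fat SAT and fatty acid synthesis lower by camera with its preset correlation. None of these list calls held with an estimated correlation (smallest adjusted p 0.174), while single genes of each list passed the test over all genes. The macrophage glycoprotein gene Cd68 (ENSMUSG00000018774, chromosome 11, 69664213 to 69666153) rose 7.81-fold, from 17.7 ± 3.23 to 138 ± 18.8 normalised CPM (mean ± SD, n = 4 each), and Adgre1 (ENSMUSG00000004730, chromosome 17, 57358691 to 57483527), which encodes a macrophage surface marker, rose 6.07-fold. Thrsp, a regulator of lipogenesis, fell from 900 ± 375 to 122 ± 11.7 CPM, and Cfd, which encodes the adipocyte product adipsin, fell from 5178 ± 2304 to 416 ± 73.6 CPM. Azin2 fell by 0.58 on the log2 scale (SE 0.117, adjusted p = 0.0127), lower in 4 of 4 high-fat libraries than in any low-fat one. Without high-fat replicate 4, Azin2 fell by 0.547 and missed the threshold (adjusted p = 0.0514).

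Of 15 tested macrophage genes 13 rose and none fell, both over all genes and adjusted over the list alone (median log2 fold change 1.53, adjusted p = 0.174 with an estimated correlation). Examples besides Cd68 and Adgre1 were the growth factor receptor gene Csf1r (log2 fold change 1.53, SE 0.129) and the complement gene C1qa (1.34, SE 0.119). Of 16 genes of lipid-associated macrophages 11 rose, also 11 adjusted over the list alone (median 2.06, adjusted p = 0.174 with an estimated correlation). These included Itgax (4.22, SE 0.311), which encodes the integrin CD11c, Gpnmb (3.77, SE 0.400), the galectin gene Lgals3 (2.79, SE 0.319) and the metalloelastase gene Mmp12 (6.22, SE 0.795). Of 25 proliferation genes 22 rose, also 22 adjusted over the list alone (median 1.85, adjusted p = 0.174 with an estimated correlation), among them the mitotic genes Ccnb2 (2.33, SE 0.203), Kif11 (2.48, SE 0.234) and Bub1b (1.76, SE 0.175). Of 22 senescence-associated secretory factors 10 rose and 1 fell, or 11 and 3 adjusted over the list alone (median 1.15, adjusted p = 0.351 with an estimated correlation). The chemokine genes Cxcl2 (2.77, SE 0.291) and Ccl2 (2.06, SE 0.474, adjusted p = 0.0204) were among those that rose. Ccl2 missed the threshold without high-fat replicate 3 (adjusted p = 0.0635), high-fat replicate 4 (0.0586) or low-fat replicate 5 (0.0557).

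Of 19 extracellular matrix genes 4 rose, also 4 adjusted over the list alone (median 1.25, adjusted p = 0.361 with an estimated correlation). They were Postn (2.39, SE 0.164), Fn1 (2.23, SE 0.285) and, named after their values were seen, Fbn1 and Loxl2. B cell genes rose in 6 of 14 and in 11 adjusted over the list alone (median 1.06, adjusted p = 0.174 with an estimated correlation), and mast cell genes in 6 of 10 and in 8 adjusted over the list alone (median 1.41, adjusted p = 0.174 with an estimated correlation). Of 17 interferon response genes 5 rose, also 5 adjusted over the list alone (median 0.54, adjusted p = 0.514 with an estimated correlation), Oasl1 (1.35, SE 0.152) and, named after their values were seen, Mx1, Oas1a, Ifit2 and Oasl2. Antigen presentation by MHC class II had 3 of 13 genes higher by either adjustment (median 0.77, adjusted p = 0.361 with an estimated correlation), H2-DMb1, Cd80 and Cd86, named after their values were seen. Of 17 p53 targets and cell cycle inhibitors 4 rose, 5 adjusted over the list alone (median 0.30, adjusted p = 0.174 with an estimated correlation). They were Cdkn2a, a cell cycle inhibitor gene (1.91, SE 0.440, adjusted p = 0.0205), and, named after their values were seen, Gdf15, Sesn1 and Mdm2. The call of Cdkn2a rested on low counts, and it was lost without any 1 of the 4 high-fat libraries (adjusted p from 0.0519 to 0.0677), low-fat replicate 3 (0.0522) or low-fat replicate 5 (0.0522). Vwf was the 1 endothelial gene of 12 that rose (1.09, SE 0.102). The endothelial list (median 0.42, adjusted p = 0.655 with an estimated correlation) was no longer called without the library labelled SAT low-fat replicate 1 (median 0.159, adjusted p = 0.0766).

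Of 18 genes of fatty acid synthesis 10 fell, 12 adjusted over the list alone with 1 higher (median -1.25, adjusted p = 0.408 with an estimated correlation). Of 21 genes of oxidative phosphorylation 6 fell, 13 adjusted over the list alone (median -0.39, adjusted p = 0.514 with an estimated correlation), and of 16 genes of branched-chain amino acid breakdown 5 fell, 6 adjusted over the list alone (median -0.56, adjusted p = 0.607 with an estimated correlation). The last 5 were Bcat2, Ivd, Aldh6a1, Pccb and Acadsb, named after their values were seen. Skeletal muscle transcripts were highest in low-fat replicate 5 among these libraries (26070 CPM). The mesothelium list was called lower (median -5.01, adjusted p = 0.514 with an estimated correlation), with Lrrn4 as its 1 gene of 5 that fell (-3.45, SE 0.379), or 5 adjusted over the list alone. The library labelled SAT low-fat replicate 1, with 50820 CPM of epididymis transcripts, belonged to this comparison, and without it the median of the list was -0.934 (adjusted p = 0.157). The clock output gene Hlf fell (-2.10, SE 0.259) and the stress-responsive transcription factor gene Atf3 rose (3.17, SE 0.122).

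The genes of largest positive change were Myh15 (log2 fold change 7.13, SE 0.592), a myosin heavy chain gene, Tm4sf19 (7.01, SE 0.306), the integrin gene Itgad (6.79, SE 0.865), the dehydrogenase gene Dhrs9 (6.71, SE 0.700) and the orphan receptor gene Gpr50 (6.45, SE 0.818). The 5 of largest negative change were Cdh1 (-6.52), Adgrg2 (-5.96), Spint1 (-4.87), Rimklb (-4.87) and Mpzl2 (-4.82), several of them epithelial genes. The library labelled SAT low-fat replicate 1 held the highest low-fat value of each of these 5, such as 1629 CPM of Adgrg2. Without it, all 5 still passed, with log2 fold changes of -2.10 for Cdh1, -1.85 for Adgrg2, -1.85 for Spint1 and -2.19 for Rimklb. Cdh1, Adgrg2, Spint1 and Rimklb in turn missed the threshold without any 1 high-fat library (adjusted p from 0.101 to 0.131), and Rimklb also without low-fat replicate 6 (adjusted p = 0.0510). Leptin (Lep, 1.38, SE 0.557, adjusted p = 0.115), adiponectin (Adipoq, -0.20, adjusted p = 0.722), Cdkn1a (0.62, adjusted p = 0.234) and the polyamine genes Odc1 (-0.10, adjusted p = 0.477) and Sat1 (-0.28, adjusted p = 0.702) did not pass. Without the library labelled SAT low-fat replicate 1, Lep (1.04, adjusted p = 0.0107), Adipoq (-0.481, adjusted p = 0.00883) and Sat1 (0.554, adjusted p = 0.00106) did.

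In all, 3622 of 17066 tested genes changed with diet in edgeR's quasi-likelihood test, 1851 higher and 1771 lower, and the values of the groups did not overlap for 34.2% of genes, where chance gives 2.86%. The count was 8109 without the library labelled SAT low-fat replicate 1, of which 3612 were among the 3622, and 1863, 1802, 2290 and 2020 without high-fat replicates 3, 4, 5 and 6. In simulated data of this design the test recovered 20% of genes changed 2-fold and 68% of those changed 4-fold. Camera with a preset correlation called 15 of 32 lists and none with an estimated one, where the smallest adjusted p was 0.174 and fry called 16. The lists that were not called had these medians: histone acetylation and acetyl-CoA supply -0.24, adipose progenitor 0.45, T and NK cell 0.39, immediate early genes 0.23, unfolded protein and integrated stress response -0.50, skin and mammary epithelium -3.47, Schwann cell -1.25, circadian clock -0.32, adipocyte -0.33, skeletal muscle -1.73, insulin signalling and glucose uptake -0.26, smooth muscle and pericyte 0.09, erythrocyte 0.09, polyamine metabolism -0.16, thermogenic adipocyte -0.14, fatty acid oxidation 0.05 and cholesterol biosynthesis -0.19. The mean had the opposite sign to the median for T and NK cell (-0.01), smooth muscle and pericyte (-0.31) and fatty acid oxidation (-0.02), and the test pointed up for thermogenic adipocyte against both. Without the library labelled SAT low-fat replicate 1, the adipocyte (-0.609), adipose progenitor (0.637), Schwann cell (-1.59), insulin signalling (-0.378), histone acetylation (-0.250) and immediate early gene lists (0.354) were called. So were histone acetylation without low-fat replicate 5 (-0.221) or 6 (-0.219), adipose progenitor without high-fat replicate 4 (0.495), T and NK cell without high-fat replicate 4 (0.488) or low-fat replicate 5 (0.734), skin and mammary epithelium without low-fat replicate 5 (-4.88) or 6 (-4.87) and skeletal muscle without high-fat replicate 6 (-7.97). Without the library labelled SAT low-fat replicate 1, skin and mammary epithelium had -1.076 (adjusted p = 0.0892) and the unfolded protein list -0.053 (adjusted p = 0.503).

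The next comparison asked what loss of Azin2 changes in SAT on the high-fat diet. Dio2 (ENSMUSG00000007682, chromosome 12, 90724552 to 90738438), which encodes the deiodinase that activates thyroid hormone in thermogenic fat, was the 1 gene of 16948 called by edgeR's quasi-likelihood test, where DESeq2 called 311 and limma-voom 295. It rose from 0.642 ± 0.110 normalised CPM in wild-type (n = 5) to 3.72 ± 0.674 CPM in Azin2-/- SAT (n = 3), a log2 fold change of 2.52 (SE 0.207, adjusted p = 0.0168), higher in 3 of 3 Azin2-/- libraries. Dio2 missed the threshold without Azin2-/- replicate 1 (adjusted p = 0.0842) or 3 (0.161) and without wild-type replicate 1 (0.0924), 3 (0.0585), 4 (0.0914) or 5 (0.0667). Dio2 and Gys2 passed without wild-type replicate 2. Dio2, Krt79, Ncan and Lipf passed without Azin2-/- replicate 2, of which Lipf was named after its values were seen. Azin2 had a log2 fold change of -0.97 (SE 0.203, adjusted p = 0.244).

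The thermogenic adipocyte list was called higher (median 1.45, adjusted p = 0.381 with an estimated correlation), with Dio2 as its 1 gene of 13 past the threshold and 4 adjusted over the list alone. Skeletal muscle transcripts were at 79610 CPM in Azin2-/- replicate 2 and 71020 CPM in wild-type replicate 3. Without both, the thermogenic median was 0.564, and without Azin2-/- replicate 2 alone it was 0.515. The lists of fatty acid oxidation (median 0.63, adjusted p = 0.670 with an estimated correlation) and oxidative phosphorylation (0.41, adjusted p = 0.934 with an estimated correlation) had 0 of 18 and 0 of 21 genes past the threshold by either adjustment. Without the pair of libraries rich in muscle transcripts their medians were 0.236 and 0.112, the latter no longer called (adjusted p = 0.114). Leaving out Azin2-/- replicate 2 alone ended both calls, with medians of 0.195 and -0.042. Leaving out Azin2-/- replicate 1 gave 0.637 for oxidative phosphorylation.

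Fatty acid synthesis (median 0.41, adjusted p = 0.381 with an estimated correlation) had 0 of 18 genes past the threshold over all genes and 8 adjusted over the list alone. Its member Acss2, which makes acetyl-CoA from acetate, had a log2 fold change of 1.11 (SE 0.157, adjusted p = 0.167). Cholesterol biosynthesis (0.52, adjusted p = 0.636 with an estimated correlation) had 0 of 20, or 1 adjusted over the list alone. Proliferation (0.59, adjusted p = 0.687 with an estimated correlation), lipid-associated macrophages (0.54, adjusted p = 0.769 with an estimated correlation) and mast cells (-1.02, adjusted p = 0.636 with an estimated correlation) had 0 by either adjustment. Without Azin2-/- replicate 1 the medians were 0.314 for proliferation and 0.168 for lipid-associated macrophages, the latter no longer called (adjusted p = 0.579). Without wild-type replicate 5 the mast cell median was -0.521.

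Among the tested genes of smallest p that did not pass, Gys2 (1.46, SE 0.178, adjusted p = 0.132), the glycogen synthase best known from liver, Agpat2 (0.97, SE 0.139, adjusted p = 0.167), an acyltransferase of triglyceride synthesis, Uhrf1bp1 (0.76), Slc36a2 (0.91), Krt79 (1.59), Ncan (1.49) and the potassium channel gene Kcnk3 (0.57) had positive log2 fold changes. Sulf1, a heparan sulfatase gene, had one of -0.99 (SE 0.134, adjusted p = 0.167). Gys2 passed without wild-type replicate 2 (adjusted p = 0.00104), and Krt79 and Ncan without Azin2-/- replicate 2 (adjusted p = 0.0256 each). Cdkn1a (0.17), Cdkn2a (1.05), Odc1 (0.20), Sat1 (-0.032), Lep (0.23), Adipoq (-0.15), Ccl2 (0.93) and Adgre1 (0.27) did not pass, with adjusted p from 0.557 to 0.948.

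At an unadjusted p below 0.05 there were 1745 genes in edgeR. The calls of the other tools came in a design where simulated data gave DESeq2 a false share of 24.9% among its calls and limma-voom 7.44%. No simulated library was rich in muscle transcripts, so these shares need not hold for the real calls. Groups did not overlap for 7.28% of genes, where chance gives 3.57%. Without the pair of libraries rich in muscle transcripts, 8 genes passed, 7 higher and 1 lower. Camera called 8 of 31 lists, and camera with an estimated correlation (smallest adjusted p 0.381) and fry called none. The medians of the lists that were not called were adipose progenitor -0.07, mesothelium -1.03, skeletal muscle 0.99, p53 targets and cell cycle inhibitors 0.17, polyamine metabolism 0.14, B cell -0.58, senescence-associated secretory factors 0.18, branched-chain amino acid breakdown 0.07, erythrocyte 0.04, extracellular matrix 0.08, circadian clock 0.07, histone acetylation and acetyl-CoA supply -0.02, macrophage -0.02, adipocyte -0.05, Schwann cell -0.54, endothelial -0.04, immediate early genes 0.21, insulin signalling and glucose uptake 0.03, antigen presentation by MHC class II 0.05, unfolded protein and integrated stress response 0.08, interferon response 0.05, smooth muscle and pericyte -0.20 and T and NK cell 0.04. The mean had the opposite sign to the median for extracellular matrix (-0.02), T and NK cell (-0.10) and histone acetylation (0.07), where the test followed the mean. Lists called in 1 leave-out or more were, without Azin2-/- replicate 1, adipose progenitor (-0.216), branched-chain amino acid breakdown (0.200), macrophage (-0.350), extracellular matrix (-0.285), skeletal muscle (1.57) and circadian clock (0.207). Without Azin2-/- replicate 2 they were interferon response (0.183) and extracellular matrix (0.348), and without Azin2-/- replicate 3 endothelial (-0.221) and skeletal muscle (1.57). Leaving out wild-type libraries called erythrocyte (0.640, replicate 1), adipose progenitor (-0.057, replicate 2), skeletal muscle (9.96, replicate 3), mesothelium (-1.10, replicate 4) and branched-chain amino acid breakdown (0.140, replicate 5).

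The same question was then asked in GAT. Lists of macrophage, proliferation and extracellular matrix genes were called higher in Azin2-/- GAT, and those of B cells and branched-chain amino acid breakdown lower, by camera with its preset correlation. None of these list calls held with an estimated correlation (smallest adjusted p 0.375). Adgre1 rose 3.66-fold, from 75.9 ± 13.7 to 278 ± 108 normalised CPM (mean ± SD, n = 4 each), and Col1a1, which encodes a chain of type I collagen, rose 2.15-fold, from 652 ± 59.6 to 1400 ± 343 CPM. Azin2 fell by 0.74 on the log2 scale (SE 0.141, adjusted p = 0.0408). The calls lay close to the threshold: edgeR's quasi-likelihood test called 1136 of 16778 genes, 915 higher and 221 lower, at adjusted p of 0.0408 or more, and 0 with no filter on low counts (smallest adjusted p 0.0626, 5269 genes at an unadjusted p below 0.05). With the filter limma-voom called 6454, and DESeq2, which applied its own filtering, called 3002. The share of higher genes among the calls was 80.5% in edgeR, 61.9% in DESeq2 and 51.7% in limma-voom, and in edgeR 65.4% without the library labelled Azin2-/- replicate 1, 68.3% without wild-type replicate 1 and 66.1% without wild-type replicate 3. The count was 0 without wild-type replicate 2 or 4 or Azin2-/- replicate 3 or 4, 1 without Azin2-/- replicate 2 (Depp1, named after its values were seen), and 2672 without the library labelled Azin2-/- replicate 1, of which 1127 were among the 1136. Each of the 30 called genes chosen by the naming rule missed the threshold in several of the 8 leave-outs, while its log2 fold change kept its sign in all of them. Leave-out values were kept only for genes named by the rule.

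Of 15 macrophage genes 12 rose, 13 adjusted over the list alone (median 1.17, adjusted p = 0.375 with an estimated correlation), including Csf1r (log2 fold change 1.17, SE 0.199) and the Fc receptor gene Fcgr1 (1.89, SE 0.341). Of 16 genes of lipid-associated macrophages 8 rose, 15 adjusted over the list alone (median 1.75, adjusted p = 0.375 with an estimated correlation), including Lipa (1.78, SE 0.321), the lysosomal acid lipase gene, and the cathepsin gene Ctsk (1.71, SE 0.333). Of 25 proliferation genes 20 rose, 24 adjusted over the list alone (median 1.29, adjusted p = 0.375 with an estimated correlation), with Nusap1 (1.15, SE 0.194), Aurkb (1.29, SE 0.233) and Pcna (0.91, SE 0.170) as examples. Of 19 extracellular matrix genes 10 rose, and adjusted over the list alone 15 were higher and 1 lower (median 0.57, adjusted p = 0.375 with an estimated correlation), among them Col3a1 (1.03, SE 0.184) and the fibrillin gene Fbn1 (0.87, SE 0.157). Of 22 senescence-associated secretory factors 5 rose, 14 with 1 lower adjusted over the list alone (median 0.87, adjusted p = 0.375 with an estimated correlation). They were the collagenase gene Mmp13 (1.61, SE 0.280) and, named after their values were seen, Ccl8, Timp1, Spp1 and Tgfb1. H2-DMb1, also named afterwards, was the 1 gene of 13 that rose in the list of antigen presentation by MHC class II, where 7 passed adjusted over the list alone (median 0.58, adjusted p = 0.445 with an estimated correlation).

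**Figure D3:**
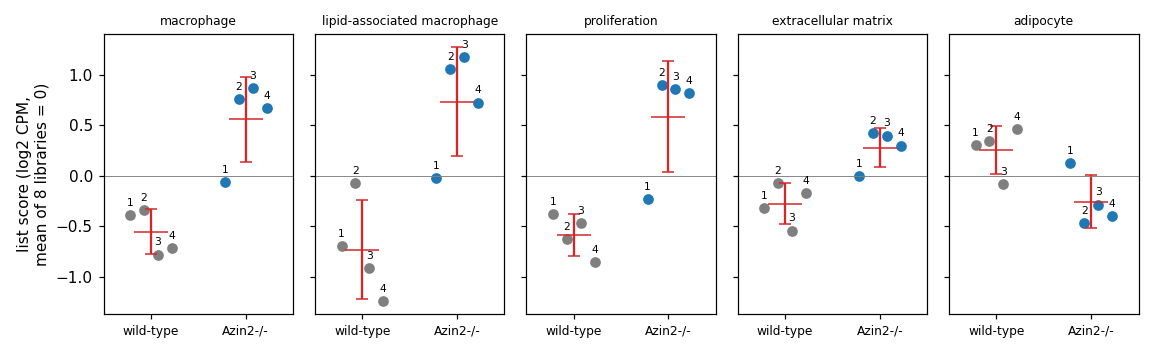
List score (mean log2 CPM of the members, with the mean of the 8 GAT libraries at 0) for 5 lists in each GAT library, with replicate numbers beside the points and the group mean ± SD in red. The library labelled Azin2-/- replicate 1 has a macrophage score of -0.061, where the other Azin2-/- libraries lie between 0.668 and 0.864.

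Of 20 genes of cholesterol biosynthesis 7 rose and 1 fell, 13 and 1 adjusted over the list alone (median 0.55, adjusted p = 0.375 with an estimated correlation). The one that fell was Fdft1 (-0.62, SE 0.103), which encodes squalene synthase, the enzyme at the entry to the sterol branch. Otop1, a proton channel gene of the thermogenic adipocyte list, rose (2.21, SE 0.348) as 1 of 11, or 3 adjusted over the list alone. That list (median 0.24, adjusted p = 0.375 with an estimated correlation) lost its call without wild-type replicate 3 (median 0.208, adjusted p = 0.146). In polyamine metabolism, which was not called as a list (median 0.11), Atp13a2, a lysosomal polyamine exporter gene, rose (0.92, SE 0.176), as did Atp13a3 and the spermine synthase gene Sms, both named after their values were seen. The list had 6 of 20 genes higher and 2 lower adjusted over the list alone. Odc1 (-0.083, adjusted p = 0.649) and Sat1 (-0.25, adjusted p = 0.726) did not pass.

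The B cell list was called lower (median -1.51, adjusted p = 0.441 with an estimated correlation). Branched-chain amino acid breakdown had 3 of 16 genes lower, 12 adjusted over the list alone (median -0.39, adjusted p = 0.394 with an estimated correlation), Aldh6a1, Ivd and Hibch, named after their values were seen. Insulin signalling and glucose uptake had 3 of 15 lower, 7 with 1 higher adjusted over the list alone (median -0.28, adjusted p = 0.375 with an estimated correlation), which were Pik3r1 (-0.40, SE 0.069), Tbc1d4 (-0.37, SE 0.071), a regulator of glucose transporter traffic, and, named after its values were seen, Pde3b. Adipocyte genes fell in 2 of 21, with 10 lower and 1 higher adjusted over the list alone (median -0.48, adjusted p = 0.441 with an estimated correlation). These were Pnpla2, which encodes an adipose triglyceride lipase, and Lgals12, named after their values were seen. Fatty acid synthesis fell in 2 of 17, Thrsp and Aacs, named in GAT after their values were seen, and in 6 adjusted over the list alone (median -0.20, adjusted p = 0.441 with an estimated correlation). Its call was lost without wild-type replicate 1 (median -0.116, adjusted p = 0.0961) or Azin2-/- replicate 2 (-0.113, adjusted p = 0.0544), and the median was -0.115 without wild-type replicate 3 and -0.071 without Azin2-/- replicate 4. Mesothelium (-1.76, adjusted p = 0.441 with an estimated correlation) had 0 of 11 genes past the threshold over all genes and 10 adjusted over the list alone, and oxidative phosphorylation (-0.19, adjusted p = 0.538 with an estimated correlation) had 0 of 21 by either adjustment.

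The largest positive changes were in Myh15 (3.72, SE 0.629), Gpr50 (3.64, SE 0.755), Tph2 (3.50, SE 0.567; ENSMUSG00000006764, chromosome 10, 115078641 to 115185022), which encodes a serotonin-synthesis enzyme best known from neurons, Itgad (3.18, SE 0.604) and Tm4sf19 (2.97, SE 0.457; ENSMUSG00000079625, chromosome 16, 32400506 to 32408227). Tph2 was at 122, 128 and 175 CPM in Azin2-/- replicates 2, 3 and 4, at 22.3 CPM in the library labelled Azin2-/- replicate 1, and at 6.90 to 12.2 CPM in wild-type. The largest negative changes were in Acsm3 (-2.61, SE 0.648), Fam13a (-2.26, SE 0.337), Mycl (-1.94, SE 0.415), Cyp2e1 (-1.88, SE 0.447), a cytochrome P450 gene, and Tmem88b (-1.86, SE 0.290). Junb (1.06, SE 0.191) and the calcium buffer gene Pvalb (2.45, SE 0.487) also rose. Ccl2 (1.72, adjusted p = 0.0652), Cdkn1a (0.44, adjusted p = 0.0680), Lep (0.70, adjusted p = 0.0788), Adipoq (-0.69, adjusted p = 0.0869) and Cdkn2a (0.55, adjusted p = 0.163) did not pass. Without the library labelled Azin2-/- replicate 1, Ccl2 (adjusted p = 0.0484), Cdkn1a (0.0110) and Adipoq (0.0345) did, and so did Ccl2 (0.0328), Cdkn1a (0.0472) and Lep (0.0358) without wild-type replicate 1 and Adipoq (0.0480) without wild-type replicate 3.

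Epididymis transcripts reached 5745 CPM in wild-type replicate 3, without which 1343 genes were called. Groups did not overlap for 15.1% of genes, where chance gives 2.86%, and in simulated data of this design the test recovered 59% of genes changed 2-fold and 83% of those changed 4-fold. Camera called 15 of 33 lists, camera with an estimated correlation none (smallest adjusted p 0.375) and fry 8. The other lists had medians of 0.17 (p53 targets and cell cycle inhibitors), -1.95 (skin and mammary epithelium), -0.12 (unfolded protein and integrated stress response), -0.11 (endothelial), 0.13 (immediate early genes), -0.42 (skeletal muscle), -0.18 (circadian clock), 0.17 (erythrocyte), -0.22 (T and NK cell), -0.02 (histone acetylation and acetyl-CoA supply), -0.34 (lymph node stroma), -0.07 (mast cell), 0.03 (adipose progenitor), -0.04 (smooth muscle and pericyte), -0.02 (fatty acid oxidation), -0.17 (Schwann cell) and -0.05 (interferon response). The mean had the opposite sign to the median for polyamine metabolism (-0.02), adipose progenitor (-0.03) and interferon response (0.05). Skin and mammary epithelium had -0.18 without wild-type replicate 3 (adjusted p = 0.905). Without wild-type replicate 1 it was called (-3.15), without replicate 2 immediate early genes (0.295), without replicate 3 endothelial (-0.219) and without replicate 4 erythrocyte (0.680).

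**Figure D4:**
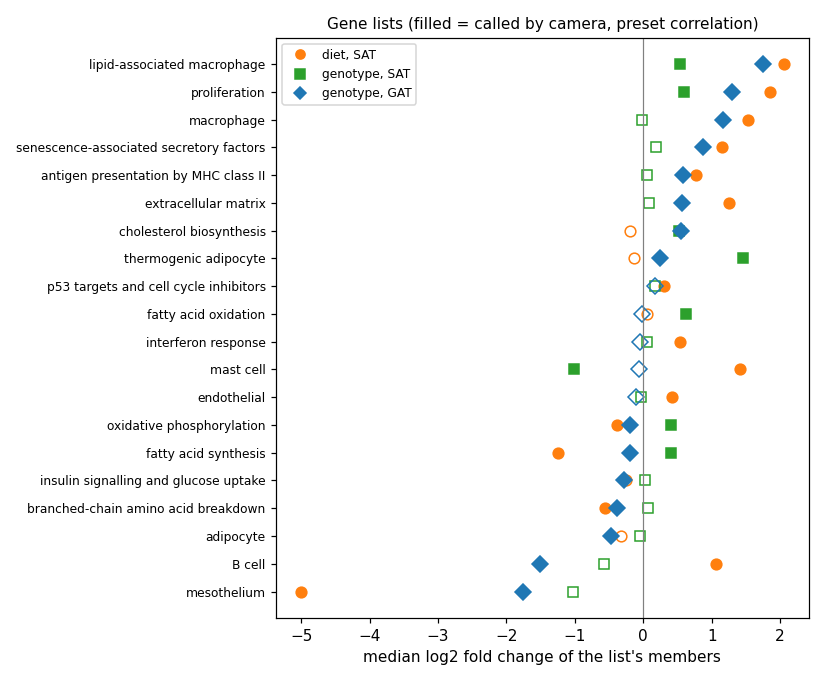
Median log2 fold change (horizontal axis) of the members of 20 gene lists for diet in SAT, genotype in SAT and genotype in GAT, filled where camera with the preset correlation called the list. Lipid-associated macrophage genes have medians of 2.06, 0.54 and 1.75 in the 3 comparisons, and B cell genes of 1.06, -0.58 and -1.51.

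Genes that the long diet moved in SAT were then followed in the genotype comparisons, which use other animals. In Azin2-/- GAT, genes raised by diet had a median log2 fold change of 1.26, positive for 193 of 199, and genes lowered by diet one of -0.49, negative for 195 of 196 (adjusted p = 0.0646 with an estimated correlation for both, below threshold with the preset one). Genes called higher by diet in SAT and by genotype in GAT numbered 610, where independent lists would share 101, and genes called lower numbered 104, against 23.2. Both counts rest on the edgeR calls in GAT, of which 0 were left without wild-type replicate 2 or 4 or Azin2-/- replicate 3 or 4 and 1 without Azin2-/- replicate 2 (3300 to 4081 genes at an unadjusted p below 0.05 in these 5 fits). Itgad, Gpr50, Myh15, Tm4sf19, Adgre1 and Csf1r were among the genes higher in both. Across genes, which are not independent replicates, the log2 fold changes of both comparisons had a Pearson correlation of 0.66 and a Spearman correlation of 0.60. In Azin2-/- SAT the medians were 0.23 and -0.10 (adjusted p = 0.498 with an estimated correlation for both). Without Azin2-/- replicate 1 they were -0.096 and 0.013, without Azin2-/- replicate 2 they were 0.380 and -0.256, and the second was -0.042 without wild-type replicate 5. The Pearson and Spearman correlations were 0.21 and 0.19 between diet and genotype in SAT and 0.34 and 0.35 between the genotype comparisons of the depots.

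Whether the genotype effect differed between depots was tested directly over the 16 libraries of the genotype experiment. No gene of 18033 passed in edgeR's quasi-likelihood test (0 called, smallest adjusted p 0.312), with 2016 at an unadjusted p below 0.05. DESeq2 called 161 and limma-voom with sample quality weights 2718. Some animal marks occur in both depots. With the mark as a block and no quality weights, limma-voom called 0 genes (smallest adjusted p 0.322). Azin2 had a difference of 0.23 (SE 0.249, adjusted p = 0.741). Without the library labelled GAT Azin2-/- replicate 1 there were 107 genes, 93 with a more positive effect in GAT and 14 with a more negative one, without SAT Azin2-/- replicate 1 there was 1 (Olfml2b), and without SAT wild-type replicate 3 there were 2 (Gpc1 and Hist1h2be), named after their values were seen. In simulated data of this contrast the test recovered 22% of genes changed 2-fold and 58% of those changed 4-fold.

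A possible effect of DNA flanking the knockout allele was examined on chromosome 4. Within 10 Mb of Azin2, 28 of 280 tested genes (10%) were called in GAT, against 1107 of 16460 other genes (6.72%), an odds ratio of 1.54 (two-sided Fisher exact test, p = 0.0403). It was 1.64 without wild-type replicate 1, 1.11 without the library labelled Azin2-/- replicate 1 (exact p = 0.512) and 1.18 without wild-type replicate 3 (exact p = 0.436). Without Azin2-/- replicate 2 it was 0, which says little, since only 1 gene was called in that fit. No value could be had where no gene was called. Within 5 Mb it was 1.04 (exact p = 0.872). In SAT, 0 of 283 genes near Azin2 were called, in a comparison with 1 called gene.

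Wild-type GAT and SAT were compared last, on the high-fat diet for 8 weeks. Genes of mesothelium, the serosal lining of the abdominal fat pads, were higher in GAT as a list (median log2 difference 8.46, adjusted p = 0.0487 with an estimated correlation). Upk3b was at 131 ± 89.5 normalised CPM in GAT (n = 4) and 0.056 ± 0.044 CPM in SAT (n = 5), Upk1b at 28.3 ± 17.6 and 0.011 ± 0.015 CPM, and the transcription factor gene Wt1 at 20.2 ± 9.52 and 0.021 ± 0.030 CPM. Muc16 was at 13.7 ± 8.88 CPM in GAT and had 0 counts in all 5 SAT libraries. Tbx15 (42.1 ± 53.1 against 0.177 ± 0.047 CPM), Hoxa10 (25.4 ± 3.68 against 0.429 ± 0.696 CPM), Lhx8 (9.32 ± 4.53 against 0.031 ± 0.061 CPM) and the noncoding AI606473 (4.69 ± 1.69 against 0.012 ± 0.024 CPM) were higher in SAT. SAT replicate 3, rich in skeletal muscle transcripts, held 116 CPM of Tbx15 before normalisation and the other wild-type SAT libraries 16.6 to 21 CPM. The immunoglobulin segment Igkv14-126, which can share reads with related segments, was at 6.03 ± 5.70 CPM in GAT and 0.004 ± 0.009 CPM in SAT. Azin2 had a log2 difference of 0.27 (SE 0.150, adjusted p = 0.324).

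Of 17030 tested genes 738 differed, 420 higher and 318 lower in GAT, and groups did not overlap for 10.6% of genes, where chance gives 1.59%. Libraries of both depots share 3 animal marks, and with the mark as a replicate block edgeR called 0 genes (smallest adjusted p 0.137, 2441 at an unadjusted p below 0.05), where without the block DESeq2 called 1859 and limma-voom 2454. Only the 3 shared marks inform the depot difference in the blocked fit, so the lost calls can reflect low power and do not show that the depots are alike. The count was 296 without GAT replicate 2, 388 without GAT replicate 4, and 354, 448 and 359 without SAT replicates 1, 4 and 5. Igkv14-126 missed the threshold without SAT replicate 2 (adjusted p = 0.0734) and Hoxa10 without SAT replicate 1 (0.0512) or 5 (0.0503). Camera called 21 of 32 lists, camera with an estimated correlation 4 and fry 5.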

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

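The tests of other tissues, of sample labels and of sequencing depth, and the tests of gene lists on the difference between depots, were chosen after the results were seen, and the splits of the samples were planned.

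The low-fat SAT group held a library far from the others. The library labelled SAT low-fat replicate 1 was the highest of its group in epididymis transcripts (50820 CPM), Cdh1 (160.9 CPM), Adgrg2 (1629 CPM), Spint1 (67.88 CPM), Rimklb (18.0 CPM), Mpzl2 (56.37 CPM), Gpnmb (54.31 CPM) and Sat1 (258.9 CPM), and the lowest in its scores of branched-chain amino acid breakdown (-0.479) and endothelium (-1.403). A scale was set with the wild-type SAT mean at 0 and the wild-type GAT mean at 1. On it, the library's 231 genes that are higher in SAT had a median position of 1.57 (quartiles 0.90 and 2.55). This argues against a small amount of epididymal tissue carried into a subcutaneous sample. Wild-type GAT libraries had 0.92 to 1.12 for these genes, short of 1.57. The library's 308 genes that are higher in GAT had a median position of 0.66 (quartiles -0.08 and 1.45). A gonadal fat sample under a subcutaneous label could give this, but the scale cannot separate it from a sample made up largely of epididymis. No biological explanation was tested, and the diet and feeding time of the library differ from those of the wild-type groups that set the scale.

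Skeletal muscle transcripts stood out in high-fat replicate 6 (7397 CPM), low-fat replicate 5 (26070 CPM) and SAT wild-type replicate 3 (71020 CPM). SAT Azin2-/- replicate 2 held more (79610 CPM), but its group of 3 libraries was too small for the Dixon outlier rule used here. Without SAT wild-type replicate 3 and SAT Azin2-/- replicate 2, the median of the thermogenic adipocyte list in Azin2-/- SAT was 0.56 and still called by camera with the preset correlation, as it was without Azin2-/- replicate 2 alone (0.515), which argues against muscle only as its whole cause, and only in that test (with all libraries adjusted p = 0.381 with an estimated correlation). For fatty acid oxidation it was 0.24 and called without both, but 0.195 and not called without Azin2-/- replicate 2 alone (adjusted p = 0.0581), so muscle stays open there. The median of oxidative phosphorylation was 0.11 and no longer called, consistent with muscle as its source. With an estimated correlation their adjusted p were 0.670 and 0.934, and fry called none of the 3 lists. An effect of the genotype on the fat cells themselves stays open for all 3.

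In GAT, the library labelled Azin2-/- replicate 1 was the lowest of its group in the scores of proliferation (-0.233) and senescence-associated secretory factors (0.032) and the highest in Acsm3 (3.029 CPM). Over the 100 genes of smallest p in the SAT genotype comparison its score was 0.10, within the wild-type GAT range of -0.12 to 0.23 and below the other Azin2-/- libraries (0.42 to 0.55), while its Azin2 level of 19.82 CPM lay 3.11 SD below the wild-type mean of 25.02 CPM. That comparison had 1 called gene, so the score is not shown to follow genotype. GAT Azin2-/- replicates 2 and 3, but not 1 or 4, share animal marks with its SAT libraries, and replicate 4 scored 0.46. A wild-type sample under a knockout label and a milder response of a knockout animal, which was not tested, therefore cannot be told apart. The score lies within the wild-type range. The Azin2 level lies between the groups, below the lowest wild-type library (22.85 CPM) and above the other Azin2-/- libraries (12.72 to 14.76 CPM). The total count of the library, 36.07 megareads, lay within the range of the other GAT libraries, which argues against sequencing depth.

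Other libraries far from their group were high-fat replicate 5 in total count (40.17 megareads) and epididymis transcripts (0.6473 CPM, near the floor), high-fat replicate 6 in the endothelial score (lowest, 0.245), high-fat replicate 4 in Cxcl2 (1.845 CPM), and GAT wild-type replicate 3 in epididymis transcripts (5745 CPM) and Sat1 (325.7 CPM). GAT wild-type replicate 1 was lowest in the mesothelium score (-1.325), GAT wild-type replicate 4 lowest in Fcgr1 (3.59 CPM) and GAT Azin2-/- replicate 3 highest in Pik3r1 (151.2 CPM). In SAT wild-type, replicate 2 was highest in Gys2 (25.73 CPM), replicate 5 in Slc36a2 (282.7 CPM) and replicate 3 in Odc1 (184.5 CPM), with the lowest Sat1 (58.27 CPM). In all, 29 of 254 groups of values held such a library, 10 of them the library labelled SAT low-fat replicate 1, where chance alone gives about 1 in 20 groups. SAT Azin2-/- was not among the groups examined, since it was too small for the rule. Outside these groups of values, the noncoding Gm42418, which overlaps ribosomal RNA and was named after its values were seen, stood at 23720 CPM in GAT Azin2-/- replicate 4, 5530 CPM in SAT wild-type replicate 1 and 1032 to 2757 CPM in the other 22 libraries. Without GAT Azin2-/- replicate 4, edgeR called 0 genes for genotype in GAT (smallest adjusted p 0.128, 3391 at an unadjusted p below 0.05) and camera with the preset correlation 15 lists.

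The genotype effect on lists differed between depots for 17 of 33 lists in camera with the preset correlation and for 0 with an estimated one (smallest adjusted p 0.0597), and fry called 1. Medians of the difference (GAT minus SAT, log2) were 1.21 for macrophage, 1.15 for lipid-associated macrophage, 0.75 for proliferation, 0.70 for mast cell, 0.55 for senescence-associated secretory factors, 0.53 for antigen presentation by MHC class II, 0.49 for extracellular matrix and 0.30 for adipose progenitor. They were -1.56 for mesothelium, -0.68 for B cell, -0.67 for thermogenic adipocyte, -0.65 for fatty acid synthesis, -0.58 for oxidative phosphorylation, -0.54 for fatty acid oxidation, -0.46 for branched-chain amino acid breakdown, and -0.39 each for adipocyte and for insulin signalling and glucose uptake. The SAT side holds the libraries with 79610 CPM (Azin2-/- replicate 2) and 71020 CPM (wild-type replicate 3) of skeletal muscle transcripts, against 65 to 127.3 CPM in GAT. Without that Azin2-/- library the SAT medians went from 1.451 to 0.515 for thermogenic adipocyte, from 0.412 to -0.042 for oxidative phosphorylation and from 0.634 to 0.195 for fatty acid oxidation. The list tests on the difference were not run without these libraries.

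Other splits of the samples were fitted in the same way. For genes, the diet split called 3622 and was 1 of 35 splits with as many (highest other 0), the GAT split called 1136 and was 1 of 35 (highest other 262), and the depot split called 738 and was 1 of 100 (highest other 9). No other split fitted reached these counts, taking libraries as separate. These are the smallest shares that 35 or 100 splits can give, so chance is unlikely but not excluded. The depot splits take no account of the 3 animal marks that both depots share, and with the mark as a replicate block edgeR called 0 genes (smallest adjusted p 0.137, 2441 at an unadjusted p below 0.05), where without the block DESeq2 called 1859 and limma-voom 2454. That blocked fit rests on the 3 shared marks and had little power. For genotype in SAT, 4 of 56 splits called as many as the real 1, so chance cannot be excluded. For the difference between depots the real count was 0, which all 100 of 100 splits reach whatever the data, so these splits say nothing about chance. The highest other split in SAT called 652 genes with Azin2-/- replicate 2 and wild-type replicates 3 and 5 on one side, which points to a structure of the samples. For the difference between depots, the highest other split called 1298 genes. It kept the true GAT labels and exchanged only SAT labels. It thus still held the GAT genotype difference, so that split says nothing about such a structure. Most splits of this contrast called 0 genes. Yet 204 were called with GAT wild-type replicates 1 and 4 and Azin2-/- replicates 3 and 4 on one side. With GAT wild-type replicates 2 and 4 and Azin2-/- replicates 2 and 3 there, 155 were. Their GAT sides were balanced for genotype, and the exchanged SAT labels were not kept, so the source of these calls is open. For lists, splits with as many calls numbered 15 of 35 for diet (real 15, highest other 21), 52 of 56 for SAT (real 8, highest other 20), 9 of 35 for GAT (real 15, highest other 20) and 6 of 100 for depot (real 21, highest other 23), so chance cannot be excluded for any of these counts. For the diet signature in SAT, 28 of 56 splits gave a median as large as 0.23 for raised genes (highest other 0.53) and 27 of 56 as large as -0.10 for lowered genes (highest other 0.35 in size). In GAT, 1 of 35 did for raised genes (real 1.26, highest other 1.17) and 2 of 35 for lowered genes (real -0.49, highest other 0.51 in size). The highest other split exchanged the library labelled Azin2-/- replicate 1 for wild-type replicate 1. Chance is unlikely but not excluded for raised genes, since 35 splits can give no smaller share, and it cannot be excluded for lowered genes.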

How the results depend on the processing

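Alternatives with libraries left out for transcripts of other tissues, and the muscle covariate, were tests chosen after seeing the data. Among called genes, 27 of 34 named for diet, 0 of 1 for SAT, 0 of 30 for GAT and 0 of 10 for depot kept direction and call under every alternative run for them, and among called lists 0 of 15, 0 of 8, 0 of 15 and 4 of 21 did. Where no cause is given, the cause was not tested. In simulated data of each design, 2-fold changes were recovered for 20% (diet), 38% (SAT), 59% (GAT), 51% (depot) and 22% (difference between depots) of genes.

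Genes called by limma-voom with sample quality weights numbered 7985 (diet), 295 (SAT), 6454 (GAT), 2454 (depot) and 2718 (difference between depots), and by DESeq2 311 (SAT), 3002 (GAT), 1859 (depot) and 161 (difference between depots). With no filter there were 2335 (diet), 0 (GAT) and 490 (depot), and with all 24 libraries in 1 fit 6056 (diet) and 13 (SAT). Without the low-fat library with epididymis transcripts and with the muscle covariate, diet gave 7756. Without the 2 libraries with most muscle transcripts, SAT gave 8, and without the 2 libraries with epididymis or most muscle transcripts, depot gave 1136. Camera with an estimated correlation called 0 lists for diet, 0 for SAT, 0 for GAT and 4 for depot, and fry 0 for SAT, 8 for GAT and 5 for depot. The signature medians, unchanged by the estimated correlation (0.234 and -0.105 in SAT, 1.256 and -0.488 in GAT), were no longer called with it. Within 5 Mb of Azin2 the odds ratio in GAT was 1.04.

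Values of other sign were these, all but the Sat1 values for diet without a call. Under limma-voom the diet medians were 0.001 for polyamine metabolism, 0.368 for cholesterol biosynthesis, -0.066 for fatty acid oxidation and -0.061 for erythrocyte. In SAT they were 0.071 for adipocyte, -0.055 for antigen presentation by MHC class II, 0.121 for B cell, 0.081 for endothelial, -0.383 for skeletal muscle and -0.013 for erythrocyte. In GAT they were 0.009 for histone acetylation and acetyl-CoA supply, -0.101 for adipose progenitor, 0.080 for T and NK cell, 0.084 for mast cell, 0.044 for smooth muscle and pericyte and 0.172 for Schwann cell, and for depot -0.095 for cholesterol biosynthesis. Log2 fold changes were 0.518 for Sat1 in diet, 0.051 for Adipoq and -0.173 for Adgre1 in SAT, 0.025 for Odc1 and 0.370 for Sat1 in GAT, and -0.063 for Azin2 in the difference between depots. Without the low-fat library with epididymis transcripts and with the muscle covariate, diet gave 0.223 for cholesterol biosynthesis, -0.132 for fatty acid oxidation, -0.216 for erythrocyte and 0.515 for Sat1. Without the 2 libraries with most muscle transcripts, SAT gave -0.091 for branched-chain amino acid breakdown, -0.021 for insulin signalling and glucose uptake, 0.050 for macrophage, -0.225 for T and NK cell, 0.036 for endothelial, -0.100 for erythrocyte, -0.102 for circadian clock, 0.045 for Sat1 and 0.006 for Adipoq. The muscle covariate gave 0.035 for macrophage in SAT, and leaving out 2 libraries gave -0.224 for skin and mammary epithelium in depot.

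With the title number as a replicate block, diet called 5439 genes, with 0.428 for cholesterol biosynthesis, -0.128 for fatty acid oxidation, -0.074 for erythrocyte and 0.530 for Sat1. With the animal mark as a replicate block, depot called 0 genes in edgeR (2441 at an unadjusted p below 0.05), with -0.094 for fatty acid synthesis and 0.014 for smooth muscle and pericyte. Only marks found in both depots inform the depot difference in that fit, so it had little power. For the difference between depots, limma-voom with the mark as a block and no quality weights called 0 genes (smallest adjusted p 0.322). Deviations of libraries that share a number correlated at 0.21, -0.14 and 0.04 for diet, 0.33, -0.04 and -0.01 for wild-type marks and -0.10 and 0.03 for Azin2-/- marks. These values are too uneven to show that the numbers or marks pair the samples, and they do not exclude that libraries with the same mark came from the same animal.

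Leaving out each replicate in turn gave these ranges, from lowest to highest. Called genes ranged from 1802 to 8109 (diet), 0 to 4 (SAT), 0 to 2672 (GAT), 296 to 909 (depot) and 0 to 107 (difference between depots), and called lists in SAT from 8 to 13. The signature medians in SAT ranged from -0.096 to 0.380 for raised and -0.256 to 0.013 for lowered genes. The odds ratio near Azin2 in GAT ranged from 0, in a fit with 1 called gene, to 1.64, with no value in the leave-outs without a called gene. The library size difference in GAT ranged from -3.44 to 0.717 megareads. Diet medians ranged from -0.398 to 0.394 for cholesterol biosynthesis, -0.093 to 0.222 for fatty acid oxidation, -0.438 to 0.239 for thermogenic adipocyte, -0.023 to 0.155 for smooth muscle and pericyte, -7.973 to 1.947 for skeletal muscle and -0.145 to 0.272 for erythrocyte. SAT medians ranged from -0.012 to 0.210 for polyamine metabolism, -0.081 to 0.315 for senescence-associated secretory factors, -0.083 to 0.050 for histone acetylation, -0.138 to 0.010 for adipocyte, -0.042 to 0.637 for oxidative phosphorylation, -0.085 to 0.200 for branched-chain amino acid breakdown, -0.121 to 0.042 for insulin signalling, -0.350 to 0.155 for macrophage and -0.236 to 0.189 for antigen presentation by MHC class II. Further SAT medians ranged from -0.300 to 0.243 for T and NK cell, -0.841 to 0.300 for B cell, -0.157 to 0.183 for interferon response, -0.285 to 0.348 for extracellular matrix, -0.221 to 0.092 for endothelial, -9.252 to 9.955 for skeletal muscle, -0.183 to 0.640 for erythrocyte, -0.017 to 0.093 for the unfolded protein response and -0.143 to 0.207 for circadian clock. The mesothelium list had too few members for a value in 2 of the 8 SAT leave-outs. GAT medians ranged from -0.078 to 0.079 for adipose progenitor, -0.117 to 0.079 for fatty acid oxidation, -0.365 to 0.063 for T and NK cell, -0.547 to 0.009 for lymph node stroma, -0.309 to 0.134 for mast cell, -0.145 to 0.068 for smooth muscle and pericyte, -0.255 to 0.036 for Schwann cell, -0.048 to 0.680 for erythrocyte, -0.056 to 0.295 for immediate early genes and -0.183 to 0.030 for the unfolded protein response. Depot medians ranged from -0.149 to 0.053 for polyamine metabolism, -0.003 to 0.213 for cholesterol biosynthesis, -0.531 to 4.967 for skin and mammary epithelium and -0.847 to 0.275 for erythrocyte. Log2 fold changes ranged from -0.492 to 0.554 for Sat1 and -0.481 to 0.026 for Adipoq in diet. In SAT they ranged from -0.043 to 0.322 for Cdkn1a, -0.070 to 0.575 for Odc1, -0.194 to 0.103 for Sat1, -0.031 to 0.450 for Lep and -0.234 to 0.516 for Adgre1, and in GAT from -0.148 to 0.030 for Odc1 and -0.428 to 0.428 for Sat1.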

Other observations

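The list tests between wild-type depots and their leave-outs of 1 library were planned, and the tests of lists on the difference of the genotype effect between depots were chosen after seeing the data.

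Wild-type GAT and SAT differed in lining, nerve, thermogenic and clock genes. Mesothelium genes, which mark the serosal lining, were higher in GAT (median log2 difference 8.46, 9 of 11 genes called, 11 adjusted over the list alone, adjusted p = 0.0487 with an estimated correlation). Schwann cell genes were lower in GAT (median -2.59, 6 of 8 called, 8 adjusted over the list alone, adjusted p = 0.0487 with an estimated correlation). Thermogenic adipocyte genes were lower too (median -1.97, adjusted p = 0.0382 with an estimated correlation), with 4 of 12 called, Cidea, Ppargc1a, Prdm16 and Otop1, named after their values were seen, and 7 adjusted over the list alone. Without SAT wild-type replicate 3, rich in muscle transcripts, that median was -1.079. Circadian clock genes were lower (median -0.36, adjusted p = 0.0487 with an estimated correlation), with 3 of 15 called, Dbp, Tef and Per3, named after their values were seen, and 5 adjusted over the list alone.

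The other 17 called lists lost their call with an estimated correlation, at adjusted p from 0.390 to 0.641. Immune lists were higher in GAT, with medians of 0.42 for macrophage (Adgre1 called of 15), 0.58 for antigen presentation by MHC class II (0 of 13), 0.89 for B cell (0 of 14) and 0.49 for lipid-associated macrophage (0 of 16). Without GAT replicate 3 or SAT replicate 4 the B cell median was 0.537 or 1.742, and without GAT replicate 2 lipid-associated macrophage missed the threshold (0.353, adjusted p = 0.0506). Also higher were proliferation (0.35; 0.539 without SAT replicate 2 and 0.206 without SAT replicate 5), p53 targets and cell cycle inhibitors (0.22, not called without GAT replicate 1, adjusted p = 0.0670), and unfolded protein and integrated stress response (0.37, with Hsp90b1, Sdf2l1, Psat1 and Phgdh higher and Atf4 lower, named after their values were seen). Fatty acid synthesis (0.15, Acly higher and Mlxipl lower, named after their values were seen) was not called without GAT replicate 1 (0.095) or 4 (0.069) or SAT replicate 1 (0.129) or 4 (0.097). Without GAT replicates 2 and 3 in turn its median was 0.092 and 0.263, and 0.222 without SAT replicate 5. Immediate early genes (0.27, Egr2 called, named after its values were seen) were not called without GAT replicate 2 (0.096) or SAT replicate 2 (0.271), 3 (0.228) or 5 (0.238), and had 0.444 without GAT replicate 3.

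Lower in GAT were oxidative phosphorylation (-0.43; -0.253 without SAT replicate 3), fatty acid oxidation (-0.42, with Acaa2 and Acot2 called, named after their values were seen) and branched-chain amino acid breakdown (-0.17, with Bckdha). Endothelial genes (-0.26) were not called without GAT replicate 3 (-0.147, adjusted p = 0.110). Extracellular matrix (-0.23, with Col1a1, Col3a1, Col5a2, Col6a3 and Lox lower, named after their values were seen) was not called without GAT replicate 3 (-0.147, adjusted p = 0.168) or SAT replicate 2 (adjusted p = 0.0657). Adipocyte genes (-0.25, with Cfd) were not called without GAT replicate 3 (-0.141) or SAT replicate 5 (-0.192). Mast cell genes (-0.68) were not called without GAT replicate 1 (-0.592), 2 (-0.489) or 4 (-0.648) or SAT replicate 1 (-0.670) or 5 (-0.315). Skeletal muscle genes (-8.07) had -0.108 without SAT replicate 3 and were not called without it or without GAT replicate 3 (adjusted p = 0.0870). Lists that were not called had medians of -0.15 (interferon response), 3.19 (skin and mammary epithelium), -0.18 (insulin signalling and glucose uptake), -0.17 (adipose progenitor), 0.35 (T and NK cell), -0.31 (smooth muscle and pericyte), 0.09 (cholesterol biosynthesis), -0.32 (erythrocyte), -0.05 (histone acetylation and acetyl-CoA supply), 0.20 (senescence-associated secretory factors) and -0.15 (polyamine metabolism). Some of these were called in a leave-out: adipose progenitor (-0.206), T and NK cell (0.509), interferon response (-0.236) and skin and mammary epithelium (3.204) without GAT replicate 2, skin and mammary epithelium without GAT replicate 1 (4.71), and skin and mammary epithelium (4.74), erythrocyte (-0.847) and insulin signalling (-0.175) without GAT replicate 4. Without SAT replicate 1 insulin signalling (-0.192) was, without replicate 2 cholesterol biosynthesis (0.213), without replicate 3 interferon response (-0.141), without replicate 4 insulin signalling (-0.163), T and NK cell (0.427) and interferon response (-0.212), and without replicate 5 smooth muscle and pericyte (-0.415).

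Lists whose genotype effect did not differ between depots at the threshold had medians of the difference of -1.86 (skeletal muscle), -0.30 (circadian clock), -0.21 (unfolded protein and integrated stress response), -0.04 (histone acetylation and acetyl-CoA supply), 0.30 (lymph node stroma), 0.05 (p53 targets and cell cycle inhibitors), -0.16 (endothelial), -1.39 (skin and mammary epithelium), 0.23 (Schwann cell), -0.17 (T and NK cell), 0.15 (erythrocyte), 0.11 (smooth muscle and pericyte), -0.14 (polyamine metabolism), -0.06 (interferon response) and -0.02 (cholesterol biosynthesis), and 0 for immediate early genes. The median, mean and test differed in sign for smooth muscle and pericyte (mean -0.02, test up), interferon response (mean 0.02, test up) and cholesterol biosynthesis (mean 0.03, test up).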
